A study of Bos taurus with 16 samples.

How the data were processed

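Total RNA from the abomasal mucosa of 16 calves was labelled with Cy3 by nonamer priming and hybridised to one-colour arrays, 1 calf per array, per the labels. Each scanner report lists 45255 target sequences, 40808 with 2 probes and 4447 with 1. Per the file headers, the intensity used here is the mean perfect-match signal of a sequence's probes on a linear scale, with no mismatch probes, and the deposited reports also give the ratio of the probes' SD to their mean. These intensities were not scaled to each other between arrays, as their medians of 219 to 1148 show. The medians do not tell whether background had been subtracted. The authors' own matrix of processed intensity holds the same sequences on a linear scale with medians of 276 to 292, and its log2 values correlate with those of the scanner signal at r = 0.927 to 0.972 on each array. How the authors normalised that matrix, and the scanner, the software and any genome build, are not given in the sources used here. No genome coordinates were used. Each barcode holds 1 array, so no slide batch could be fitted.

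Sequences were named from the description in the reports: 27563 have one and 17692 have none. The descriptions carry protein names and cluster numbers rather than symbols, and no identifier matched the reference table of gene symbols, so a list gene was matched by patterns on its protein name, written without looking at signal values. Descriptions marked as weakly similar were not used. Outside the lists, a protein name was used only where a stated partial match covered at least 20% of the protein and any named species of the match was a mammal. List genes had no such minimum, and sequences of FCGBP and C3 include matches to a small part of the protein. Of 527 list genes, 355 were matched by 640 sequences. The chloride channel-1 sequence was not matched to CLCA1, which the mucous list holds, and so stayed outside that list.

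Background was corrected by normexp with an offset of 50, arrays were quantile normalised, and values are log2. Sequences with a mean log2 signal above the 25th percentile were kept, because the reports hold no random control probes, leaving 33941. limma (3.58.1, R 4.3.3) fitted the 4 groups of 4 together, and moderated tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 fold changes are standard errors. Contrasts were primary infection minus naive control, 5th reinfection minus drug-attenuated control, the difference of these, and drug-attenuated minus naive control. Per the labels each array is a separate calf, so the spread is between animals. The number of arrays limits the precision: the median SE of a log2 fold change was 0.44 for a contrast of 2 groups.

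The 27 gene lists, fixed before the data were examined, were complement, type 2 immunity, type 1 and interferon response, mast cell, eosinophil, neutrophil, macrophage and dendritic cell, T and natural killer cell, B and plasma cell, MHC class II presentation, mucous cell and mucin, tuft cell, parietal cell, chief cell, enteroendocrine cell, proliferation, extracellular matrix, smooth muscle, endothelium, epithelial junction, intestinal epithelium, squamous epithelium, red blood cell, acute phase, oxidative phosphorylation, ribosomal protein, and heat shock and endoplasmic reticulum stress. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. A gene with several sequences was represented by the one with the highest mean log2 signal.

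The rule for named genes was also fixed before the data were examined. It takes, for each infection contrast, up to 10 each way with the largest fold change among sequences past the threshold, with 1 named gene and no overlap of the 4 and 4 values, and 5 each way for the other contrasts. Where fewer than 5 of a direction pass, the 5 with the smallest p are named and said not to pass. Any complement member, and up to 4 members of another list with the smallest p, may be named. A gene that the rule names is not reported here. Genes of the set higher in both infections and the immunoglobulin classes were named after their values were seen.

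The fits were tested on simulated data with the real means and spreads of the 33941 sequences, 200 of them changed, in 10 repeats. For primary infection 6.27%, 45.5% and 89.1% of changes of 1, 2 and 4 on the log2 scale were recovered, and for 5th reinfection 5.67%, 44.8% and 90.8%. False calls were 5.84% and 5.92% of all calls. When the real residuals of whole arrays were shuffled instead, 4351 of 5303 calls for 5th reinfection were false and 0 of 902 for primary infection, so the shared structure of the arrays can produce runs of false calls. In that setting camera with the preset correlation called 15 and 19 of 260 unchanged lists, and with an estimated correlation 0.

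The alternatives set before the data were seen were no background correction, cyclic loess, median scaling, no filter, a filter at the 50th percentile, the authors' values, a trended robust spread, array weights, only the compared groups, an adjusted p under 0.1, each array left out in turn, and for lists an estimated correlation or the mean over all sequences of a gene. Chosen after seeing the data were the median raw signal as a covariate, the brightness class as a block, the dim arrays only, the 2 leading residual components as covariates, and the geometric mean of both probes. No list was tested without a filter, with the stricter filter, on the authors' values or at the looser threshold. Nor were lists tested with a trended robust spread, array weights or only the compared groups, which left 26 alternatives. Splits of the arrays (35 for a pair of groups, 100 draws otherwise) used a fixed seed. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.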

Results

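Gene expression was measured in the abomasal mucosa, the lining of the glandular stomach, of Holstein bull calves with and without *Ostertagia ostertagi*, a nematode whose larvae develop in the gastric glands. The 16 one-colour oligonucleotide arrays fall into 4 groups of 4 calves. Primary infection (day 14) and naive control calves were 3 to 4 months old. Calves at day 14 of a drug-attenuated 5th reinfection, and uninfected drug-attenuated controls, were 8 to 9 months old. The labels do not say which drug was used or how it was given. The series design names both infection contrasts as its main ones, and its title names complement and protective immunity, so complement genes are not an independent choice here. Each array reports 45255 target sequences, of which 33941 were bright enough to be tested.

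Arrays of one group often differed more than groups did. The median raw signal ran from 219 to 1148 units across arrays, or from 7.77 to 10.16 on the log2 scale. Its group mean was 9.19 ± 0.89 in naive controls, 9.04 ± 1.03 in primary infection, 8.63 ± 0.59 in attenuated controls and 9.16 ± 0.85 in 5th reinfection (log2, SD, n = 4 each). Correlations of log2 signal between arrays lay between 0.333 and 0.987, with a median of 0.811 within groups and 0.858 between groups. After normalisation, 84.7% of the variance still lay within groups, where 4 groups of 4 without any effect would also leave most of it. The first principal component, with 70.5% of the variance, followed the median raw signal (Pearson's r = 0.954, Spearman's rho = 0.935, 16 arrays, permutation p = 1e-05 and 2e-05, 1e-05 being the smallest that 100000 permutations can give). Without the 2 arrays farthest from the median signal r was 0.949 and rho 0.912, and all 4 adjusted p-values were 2e-05. A gap of 0.56 in log2 signal parted 6 bright from 10 dim arrays. The bright arrays were naive control replicates 1 and 3, primary infection replicates 1 and 4 and 5th reinfection replicates 1 and 3, and no attenuated control was among them.

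**Figure D1:**
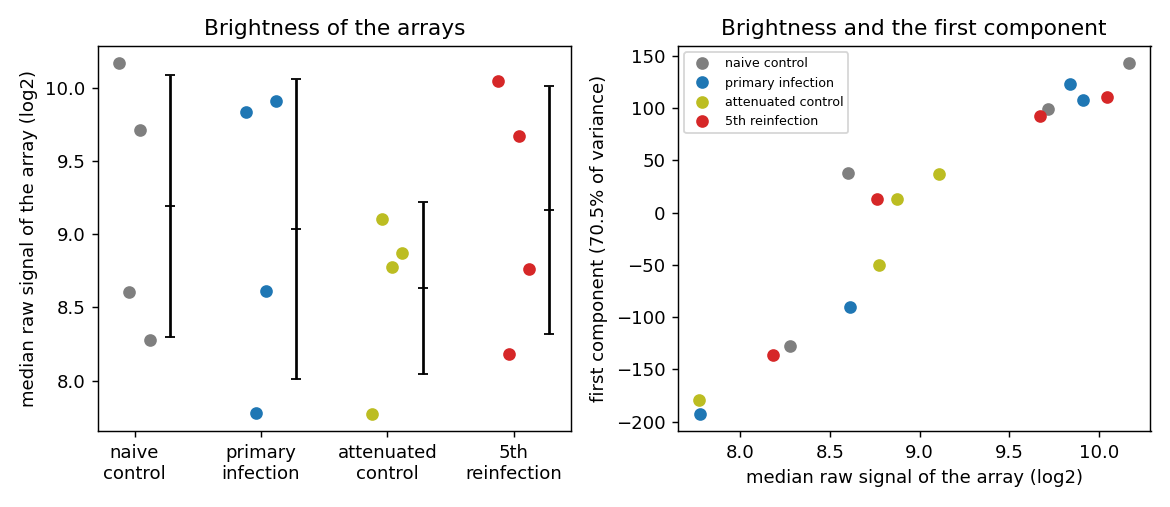
Left, median raw signal of each array (log2) by group, with the group mean and SD as black bars (n = 4). Right, the first principal component of the normalised log2 signal (70.5% of the variance) against the same median signal, one point per array, with r = 0.954 over 16 arrays.

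In primary infection, the named genes with the smallest p-values had higher values than in naive controls, and none passed the test over all sequences. FCGBP (TC289641), a mucus protein that binds IgG Fc, had a mean log2 signal of 11.19 ± 0.95 against 8.55 ± 0.42 in naive controls (SD, n = 4 each), a difference of 2.64 ± 0.43 (SE). The target sequence described as calcium-dependent chloride channel-1 (TC291840), a secretory epithelial product, differed by 3.23 ± 0.54 and CFI (TC277844), the protease that inactivates C3b and C4b, by 1.66 ± 0.27. In each of these 3, all 4 infected calves lay above all 4 controls. CFB (TC262853), which forms the alternative pathway C3 convertase, differed by 2.31 ± 0.45 and MMP-3, a matrix-degrading protease, by 1.70 ± 0.36. A second FCGBP sequence had 0.72, so the sequences of this gene differ in size.

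limma called 0 of 33941 sequences at an adjusted p under 0.05, and 51 had an unadjusted p under 0.05 (39 higher, 12 lower), where 1697 would be expected by chance. The smallest adjusted p was 0.273, shared by FCGBP, CFI and the chloride channel-1. Values of both groups did not overlap for 65 sequences, or 0.192%, where chance gives 2.86%. Both chance values are averages over groupings. With sequences that vary together over the arrays, single counts can lie far to either side of them, here and in the other contrasts. A count below them is thus no sign of fewer differences than without infection. On the lower side, the named genes with the smallest p were SPLUNC family member 2B (short palate, lung and nasal epithelium carcinoma associated protein, -1.20), member 2A (-0.87), RPS4X (-0.81), the SA protein (-1.20) and CYP4F11 (-0.84), and none passed. With the median raw signal of each array as a covariate, an alternative chosen after the data were seen, 5 sequences were called and all were higher. FCGBP, CFI and the chloride channel-1 then had adjusted p-values of 0.00205, 0.00497 and 0.0134, against ranges over all alternatives of 1.19e-07 to 1.00, 2.23e-07 to 1.00 and 4.37e-07 to 1.00.

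**Figure D2:**
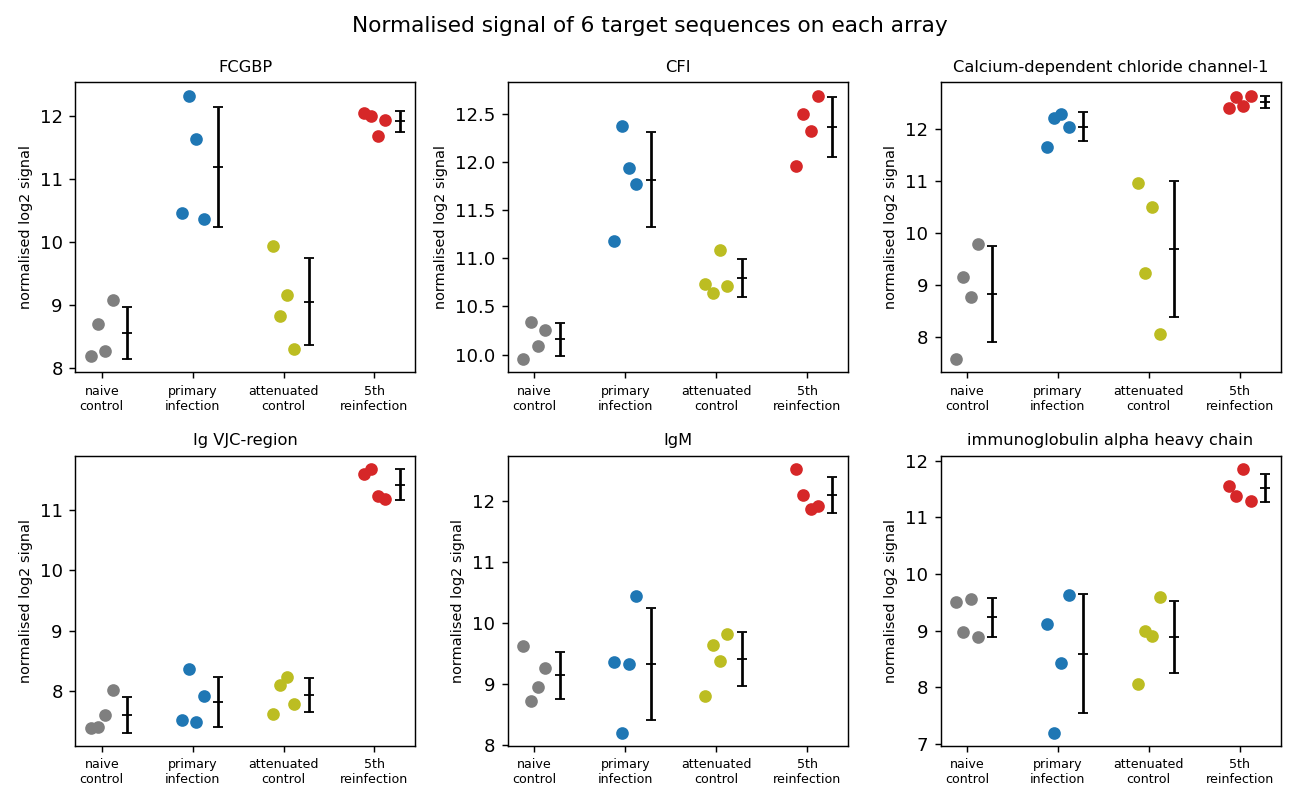
Normalised log2 signal of 6 target sequences on each array by group, with the group mean and SD as black bars (n = 4). In 5th reinfection the Ig VJC-region stands at 11.42 against 7.93 in its control, and in primary infection FCGBP stands at 11.19 against 8.55.

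Among the lists fixed before the data were examined, mucous cell and mucin genes rose as a set in primary infection. Of the 11 measured, 8 had positive values (median 0.31, camera adjusted p = 3.75e-07), and FCGBP and TFF3 (1.40 ± 0.31), a trefoil peptide of goblet cells, were higher when adjusted over the list alone. The list also passed with an estimated correlation (adjusted p = 0.0259) and under all 26 alternatives run (adjusted p from 4.10e-13 to 0.0259). ITLN2, an intelectin that binds microbial glycans, had a value of 1.65 ± 0.76, and MUC5AC, the surface mucin, 1.37 ± 0.72, and neither passed. The gastric mucous markers TFF1, TFF2 and GKN2 had -0.01 ± 0.26, 0.59 ± 0.37 and -0.13 ± 0.32, so the members did not all rise together.

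The proliferation list rose (17 of 22 positive, median 0.30, adjusted p = 0.0179), as did extracellular matrix (15 of 18 positive, median 0.22, adjusted p = 0.0118), while no member passed by itself. Both calls were lost with an estimated correlation (adjusted p = 0.495 and 0.411). MCM5 and MCM4, helicase subunits loaded at replication origins, had values of 0.70 ± 0.42 and 0.56 ± 0.35. FBLN1 and TNC, matrix glycoproteins, had values of 0.81 ± 0.38 and 0.58 ± 0.29. The neutrophil list fell: all 8 members were negative (median -0.46, adjusted p = 0.0191). This call too was lost with an estimated correlation (adjusted p = 0.691). Lists of intestinal epithelium, squamous epithelium and red blood cells, which did not pass, had medians of -0.37, -0.44 and -0.45 in the same contrast. S100A9 (-0.53 ± 0.49), MPO (-0.69 ± 0.88) and the cathelicidin CATHL2 (-0.73 ± 0.68) were among the negative neutrophil genes, and 0 passed when adjusted over the list alone. Over the 26 alternatives run for lists the adjusted p ranged from 7.05e-05 to 0.495 for proliferation, from 7.05e-05 to 0.411 for extracellular matrix and from 0.00809 to 0.949 for neutrophil genes. Leaving out primary infection replicate 2, the array farthest from its group, gave an adjusted p of 0.949 and a median of 0.03 for neutrophil genes. For proliferation it gave an adjusted p of 0.173 and a median of 0.08. Without naive control replicate 1 the adjusted p was 0.148 for neutrophil genes, 0.143 for proliferation and 0.148 for extracellular matrix, where the medians were -0.30, 0.13 and 0.05. Without naive control replicate 3 the adjusted p was 0.0641 for neutrophil genes and for proliferation, and without naive control replicate 4 it was 0.0825 for proliferation. Without primary infection replicate 3 it was 0.0879, 0.0745 and 0.0803 for neutrophil, proliferation and matrix genes.

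Complement as a list did not pass in primary infection. Its 30 measured members split into 15 positive and 15 negative (median -0.02), while the test pointed up (adjusted p = 0.113). Adjusted over the list alone, CFI and CFB (1.90 ± 0.40 in the sequence used for the list, TC262854) were higher and the other 28 did not pass. C7, C4A and C1QB, parts of the terminal, classical and C1q steps, had values of 0.79 ± 0.43, 0.96 ± 0.63 and 0.51 ± 0.31. C3, the central component, had 0.41 ± 0.68 in the sequence used for the list, while its 7 sequences ranged from 0.41 to 1.61 and 3 had an unadjusted p under 0.05. PIGR, which carries IgA and IgM across the epithelium, was the 1 gene of 6 in the B and plasma cell list to pass when adjusted over that list alone, with a mean log2 signal of 12.53 ± 0.66 against 11.03 ± 0.83 (SD, n = 4 each). That list did not pass (median 0.11, adjusted p = 0.325).

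In 5th reinfection, immunoglobulin chains rose. The Ig VJC-region sequence (TC262336), a light chain, had a mean log2 signal of 11.42 ± 0.25 against 7.93 ± 0.28 in the drug-attenuated control (SD, n = 4 each), a difference of 3.49 ± 0.27 (SE, adjusted p = 3.27e-05). IgM (TC262222) rose by 2.71 ± 0.40, immunoglobulin alpha heavy chain (TC262273), the chain of IgA, by 2.63 ± 0.44, and the IgG2a constant region (TC262529) by 2.07 ± 0.26, with adjusted p-values of 0.0220, 0.0472 and 0.00496. FCGBP rose by 2.87 ± 0.43 (adjusted p = 0.0243), with 0.54 in its second sequence, and CFI by 1.58 ± 0.27 (adjusted p = 0.0472). All 4 reinfected calves lay above all 4 controls in each of these.

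limma called 22 sequences, all higher and 0 lower, and 347 had an unadjusted p under 0.05 (225 higher, 122 lower), where 1697 would be expected by chance. The other called sequences that the rule named were an immunoglobulin heavy chain (2.50 ± 0.42), the secretory form of the IgM heavy chain (1.93 ± 0.29), and the heavy (2.18 ± 0.30) and light (2.48 ± 0.41) chain sequences filed as an anti-testosterone antibody. Values of both groups did not overlap for 548 sequences, or 1.61%, where chance gives 2.86%. On the lower side none passed (adjusted p = 0.921). The named ones were pulmonary surfactant-associated protein B (-1.20), one BOLA-DQB sequence (-1.70), dynein intermediate chain 1 (-0.76), pancreatic secretory trypsin inhibitor (-0.72) and fibrinogen alpha, FGA (-0.94). Other BOLA-DQB sequences were positive, up to 0.49, so the 4 sequences of this class II gene did not move together.

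Of the 22 calls, 16 were immunoglobulin chains, 2 were FCGBP and CFI, and 4 carried no description. This theme was found after the calls were seen. Among 22376 described sequences that were tested, 117 were immunoglobulin chains, and Fisher's exact test of the 16 against the rest gave a two-sided p of 1.63e-35. That p only describes the calls, since the family was chosen from them and related sequences are not independent. The wording that defined the family includes phrases carried by called sequences, such as anti-testosterone antibody. The family had a median of 1.25, with 106 of 117 sequences higher, and its median was 0.99 to 1.35 under the other normalisations. By class, the median was 1.87 for 24 IgG sequences, 1.68 for 10 IgA, 1.67 for 27 light chain, 0.93 for 42 other heavy chain and 0.70 for 14 IgM sequences. The chains form a multigene family whose members can share a probe, so the class of a single sequence is uncertain. In primary infection the same 117 sequences had a median of -0.25, with 38 higher. The dim arrays alone gave a median of 0.82 in 5th reinfection (2 reinfected and 4 control arrays). It was 0.76 with the median raw signal as a covariate and 0.65 with the brightness class as a block.

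The count of 22 rested on single arrays: it was 67 without primary infection replicate 2, which adds to the shared estimate of the spread, and 6 without attenuated control replicate 3, 5th reinfection replicate 1 or 5th reinfection replicate 4. It was 7 without attenuated control replicate 2 or 5th reinfection replicate 3, 8 without attenuated control replicate 1 or 5th reinfection replicate 2, and 9 without attenuated control replicate 4. Leaving out naive control replicate 2 gave 12, and naive control replicate 1, naive control replicate 3 or primary infection replicate 3 gave 14 each. The Ig VJC-region and IgG2a calls passed without any 1 of the 16 arrays (highest adjusted p 0.000423 and 0.0361). FCGBP and IgM passed in 9 of the 16 such fits (highest 0.116 for both), and CFI and the alpha heavy chain in 2 (highest 0.213 and 0.228). Over all alternatives the adjusted p reached 0.0503 for the Ig VJC-region, 0.571 for IgM, 0.914 for the alpha heavy chain and 0.928 for IgG2a, FCGBP and CFI.

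Complement genes rose as a list in 5th reinfection: 24 of 30 were positive (median 0.23, adjusted p = 0.00835). With an estimated correlation the adjusted p was 0.327, so the call was lost. CFI was the 1 member past the test, over all sequences and adjusted over the list alone. CFB had 1.33 ± 0.40, C5AR1, the receptor for C5a, 0.72 ± 0.44, and C3 0.84 ± 0.68 in the list's sequence, against 0.84 to 1.75 over its 7 sequences, 6 of them with an unadjusted p under 0.05. Without 5th reinfection replicate 2 the list's median was 0.41 and its adjusted p 0.0864. Over the 26 alternatives run for lists the adjusted p ranged from 0.000873 to 0.327. With the brightness class as a block the list's median was 0.03, while the test still pointed up (adjusted p = 0.00696). The list is not independent evidence, since the series title names complement.

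Genes of oxidative phosphorylation and of the ribosome fell as lists in 5th reinfection (adjusted p = 1.15e-05 and 0.00178), and both calls were lost with an estimated correlation (adjusted p = 0.475 for each). Of 27 oxidative phosphorylation genes 25 were negative (median -0.38), among them COX6C (-0.56 ± 0.24) and NDUFA4 (-0.88 ± 0.49), subunits of the respiratory chain. Of 25 ribosomal protein genes 22 were negative (median -0.24), among them RPS20 (-0.56 ± 0.34) and RPL19 (-0.59 ± 0.37). No member passed, over all sequences or adjusted over either list alone. With the brightness class of the arrays as a block the adjusted p was 0.574 and 0.176, where the medians were -0.01 and -0.11. Over the 26 alternatives run for lists the adjusted p ranged from 8.92e-07 to 0.574 and from 2.41e-06 to 0.475. The drug-attenuated control arrays also enter the difference and the comparison of the control groups, where both lists rose. A shift of those arrays alone would move all of these contrasts, so their list changes are not independent. In primary infection the medians were 0.05 and -0.12. In 5th reinfection the mucous cell and mucin list did not pass (median 0.30, adjusted p = 0.103), and its median was -0.25 under median scaling. Adjusted over that list alone FCGBP, ITLN2 (2.93 ± 0.76) and TFF3 (1.08 ± 0.31) were higher, while GKN2, a gastrokine of surface mucous cells, had -0.84 ± 0.32.

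**Figure D3:**
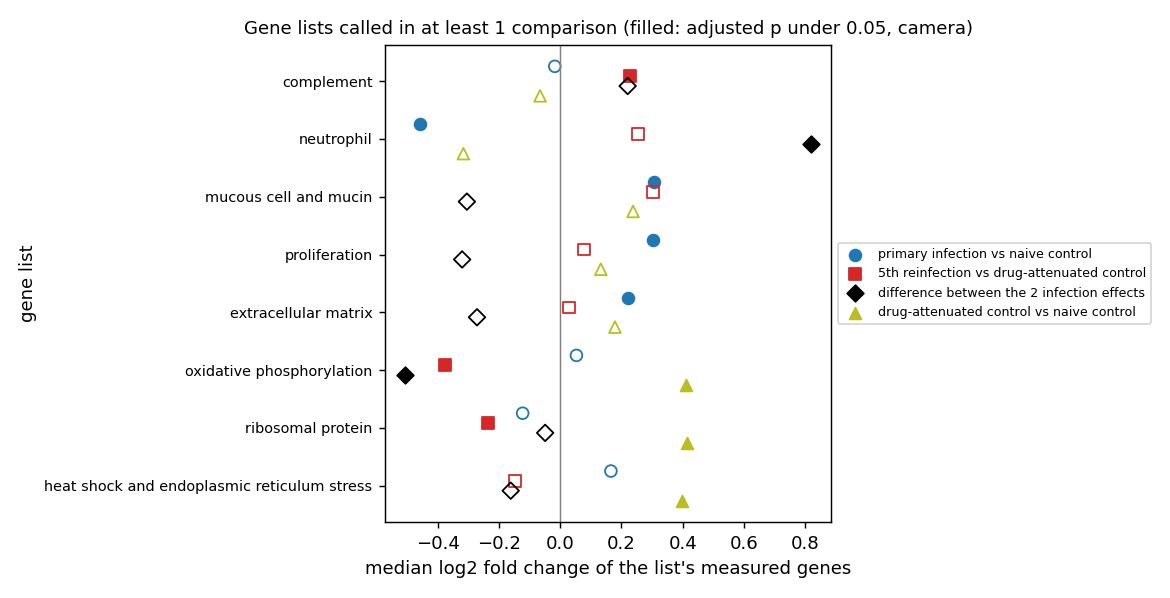
Median log2 fold change of the measured genes of each list called in at least 1 comparison (x axis) by list (y axis), one symbol per comparison and filled where the adjusted p was under 0.05. Mucous genes stand at 0.31 in primary infection, and oxidative phosphorylation at -0.38 in 5th reinfection and 0.41 in the comparison of the control groups. Both of these comparisons of oxidative phosphorylation use the drug-attenuated control arrays, with opposite sign.

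The difference between the infection effects was tested directly, since the infections differ in age, earlier exposure and drug treatment together. The Ig VJC-region sequence was raised more in 5th reinfection, by 3.28 ± 0.38 (SE, adjusted p = 0.00839), and was the 1 call of 33941. The count was between 1 and 4 when single arrays were left out: 4 without primary infection replicate 4, and 2 without naive control replicates 1, 2 or 3, primary infection replicates 1 or 2, or attenuated control replicates 2 or 4. The call was lost with loess, median scaling and the dim arrays, and the sequence was below the stricter filter, so the count was 0 in each, within an adjusted p range of 3.94e-08 to 1.00. At an unadjusted p under 0.05 there were 114 sequences (102 higher, 12 lower), where 1697 would be expected by chance. Immunoglobulin alpha heavy chain (3.27 ± 0.63, adjusted p = 0.479), IgM (2.51 ± 0.56), an immunoglobulin heavy chain (2.58 ± 0.59), the secretory IgM form (2.14 ± 0.41) and an anti-testosterone heavy chain (1.97 ± 0.43) did not pass. The family's median difference was 1.70, with 104 of 117 sequences higher. For FCGBP and CFI the infections' values lay close together, at 2.64 and 2.87 and at 1.66 and 1.58, and the CFI difference was -0.08 ± 0.38 (adjusted p = 0.923). On the other side, BOLA-DQB (-2.47), an MHC class II sequence (-1.39), TFF2 (-1.27), ETFB (-1.01) and cytochrome P450 2B22 (-1.18) had negative differences, and none passed. These are log2 fold changes in 5th reinfection minus those in primary infection, so a rise in primary infection adds to them.

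Of the lists, neutrophil genes differed upward (8 of 8 positive, median 0.82, adjusted p = 0.0138) and oxidative phosphorylation genes downward (26 of 27 negative, median -0.51, adjusted p = 8.51e-05). Both had an adjusted p of 0.638 with an estimated correlation, so both calls were lost. The intestinal, squamous and red blood cell lists, which did not pass, had median differences of 0.77, 0.88 and 1.12. With the brightness class as a block the neutrophil and oxidative phosphorylation medians were 0.27 and -0.12 and the adjusted p 0.165 and 0.124. Over the 26 alternatives run for lists it ranged from 0.00727 to 0.638 for neutrophil genes and from 5.57e-06 to 0.638 for oxidative phosphorylation. Without primary infection replicate 2 the neutrophil list had a median of 0.29 and an adjusted p of 0.115. CSF3R, the receptor for granulocyte colony-stimulating factor, had a difference of 1.03 ± 0.71 and S100A9 of 0.78 ± 0.69, while COX6C had -0.66 ± 0.35.

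Sequences higher in both infections were counted too, because the contrasts share no arrays. No sequence was called by limma in both, which had to be so with 0 calls in primary infection. At an unadjusted p under 0.05, 23 sequences were higher in both, against 0.259 for independent lists, and 0 were lower in both. That baseline leaves out that both contrasts share 1 estimate of each sequence's spread, and joint relabellings of the arrays shared a median of 1. The 23 sequences include CFI, FCGBP, the chloride channel-1, both CFB sequences, 3 C3 sequences, MMP-3, TFF3, ITLN2, claudin 2 (CLDN2), CFTR and collectin-46. They also hold 2 IgG heavy chain sequences, both among the immunoglobulin calls of 5th reinfection. In primary infection and 5th reinfection these differed by 0.65 and 2.80 (TC262286) and by 0.66 and 1.89 (TC262238). MMP-3 differed by 1.70 and 1.66, CLDN2, a pore-forming tight junction protein, by 1.04 and 1.36, and CFTR, the apical chloride channel, by 0.73 and 0.83 in primary infection and 5th reinfection. Across all tested sequences the log2 fold changes of both contrasts had r = -0.218 and rho = -0.276, over sequences that are not independent replicates. That sign was not stable: r was 0.638 with median raw signal as a covariate, 0.710 with the brightness class as a block and 0.537 without primary infection replicate 2.

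**Figure D4:**
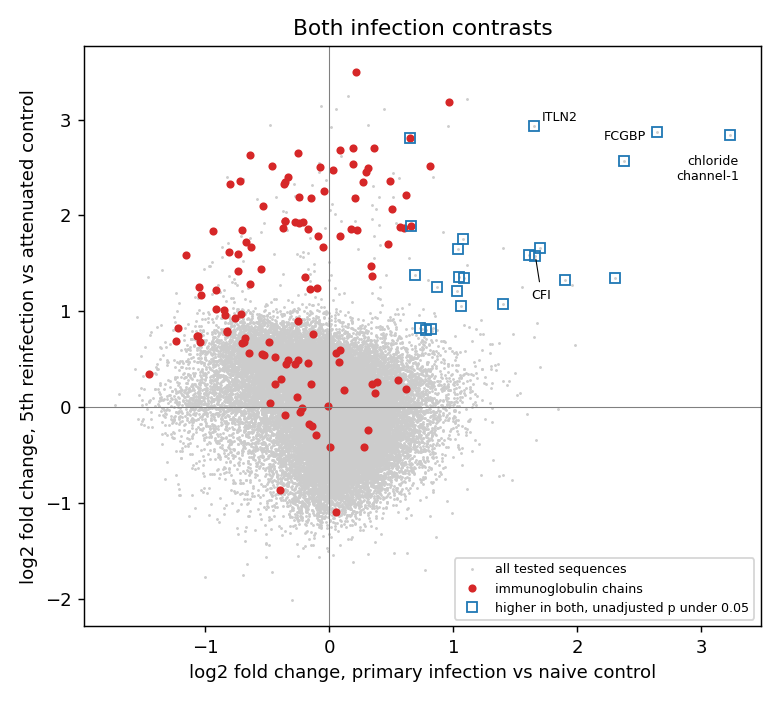
Log2 fold change of each tested sequence in 5th reinfection against its control (y axis) and in primary infection against its control (x axis). Grey points are all 33941 sequences, red points the 117 immunoglobulin chains, and blue squares the 23 sequences higher in both at an unadjusted p under 0.05.

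The uninfected groups differ in age and in treatment history together, and their comparison cannot part those. In drug-attenuated controls, no sequence passed against naive controls, and PIGR had the smallest p among named genes. PIGR differed by 2.15 ± 0.39, a further IgM secretory heavy chain (TC262223) by 1.71 ± 0.38, duodenase, a mast cell serine protease of ruminants, by 1.65 ± 0.38 and CFB by 1.84 ± 0.45. limma called 0 sequences, and 853 had an unadjusted p under 0.05 (264 higher, 589 lower), where 1697 would be expected. The adjusted p was 0.750 for each named gene. Lower values were seen for a cAMP-specific phosphodiesterase (-1.09), AAK1 (-1.40), cyclin T1 (-0.93), AF5q31 (-0.94) and sodium/hydrogen exchanger 7 (8.04 ± 0.39 against 9.04 ± 0.47, SD, n = 4 each), and none passed.

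Oxidative phosphorylation genes (25 of 27 positive, median 0.41, adjusted p = 1.62e-05), ribosomal protein genes (23 of 25 positive, median 0.41, adjusted p = 0.000544) and heat shock and endoplasmic reticulum stress genes (12 of 14 positive, median 0.40, adjusted p = 0.0351) were raised as lists in the drug-attenuated control. With an estimated correlation all 3 had an adjusted p of 0.776, so these calls were lost. SDHC had 0.80 ± 0.37, RPS20 0.65 ± 0.34 and the chaperone HSPD1 0.72 ± 0.41. The heat shock list had 0.401 without naive control replicate 1, 0.0879 without attenuated control replicate 1 and 0.0588 without attenuated control replicate 4. Complement did not pass (median -0.07, test pointing up, adjusted p = 0.149), while CR2 (1.98 ± 0.53), the receptor for C3d on B cells, was higher when adjusted over the list alone. With the brightness class as a block the medians of the 3 called lists were 0.11, 0.15 and 0.03 and their adjusted p-values 0.0720, 0.00888 and 0.698, and on the dim arrays the ribosomal list had 0.139. Over all alternatives the adjusted p ranged from 1.97e-06, 4.49e-05 and 0.00568 up to 0.776, 0.776 and 0.814.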

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

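The tests of B cell number, of the chain classes, of the mucous cell markers and of the array structure were chosen after the result was seen, as were the covariate, block and dim-array alternatives. The split into bright and dim arrays was likewise chosen after the array signals were seen, while what the dim arrays and other splits would show was set down before those tests were run.

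Immunoglobulin chains were flagged because the Ig VJC-region sequence was called for the difference between the infections (3.28, limma adjusted p = 0.00839). It was the 1 chain of 117 called there, and the call was lost with loess, median scaling and the dim arrays. A differing response of the whole family thus rests on its median and not on calls. Brightness as the whole cause predicted a median of the 117 chains below 0.5 on the dim arrays, where it was 0.818 (0.62 to 1.34 with a dim array left out, 1.11 over those chains that passed the filter on these arrays, against 1.25 on all arrays), and all 16 chain calls passed with median raw signal as a covariate, where the family median was 0.76. A part played by brightness stays open, since the median was lower in these settings and 10 of the 16 passed with the brightness class as a block (family median 0.65) and 0 on the dim arrays, which are fewer. Whether more B cells alone account for it is not decided. Per array, the median chain minus the mean of CR2, BLNK and CXCR5 was 2.23 ± 0.86 in 5th reinfection and 0.48 ± 0.71 in its control (SD, n = 4 each). The gap was 1.76 (exact permutation p = 0.0286, the smallest the design allows, higher in 4 of 4). The chains had been picked for being higher, which favours such a gap. The upper 95% limits of the CR2, BLNK and CXCR5 changes were 1.19, 0.85 and 0.95, so a rise in B cells stays open. Calls in 4 classes (IgM, IgA, IgG and light chain) argue against a single chain read by related sequences, as far as the class names hold for probes that can be shared, and antibody-secreting cells (JCHAIN 0.60 ± 0.54 and PRDM1 0.61 ± 0.33, not passing), age and earlier exposure stay open.

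The 23 sequences higher in both infections form a second pattern, which holds 2 of the immunoglobulin chains as well. Brightness predicted a median below 0.5 on the dim arrays in at least 1 contrast, where the medians were 1.96 in primary infection and 1.90 in 5th reinfection, although the sequences had been picked on these same arrays. Chance could not be excluded: 10 of 100 joint draws of the arrays, the real one included, shared at least 23 sequences in one direction, and the highest other shared 1250, a size that points to some structure of the arrays, not traced to brightness. More mucous cells and a change within them cannot be told apart in either infection, because the highest upper 95% limit among the gastric markers TFF1, TFF2, GKN2 and MUC5AC was 2.20 in 5th reinfection and 2.90 in primary infection, both set by MUC5AC and above the lower limits of TFF3 (0.42 and 0.75). TFF1, TFF2 and GKN2 had -0.26, -0.68 and -0.84 in 5th reinfection, and FCGBP, TFF3 and ITLN2 had been picked for being higher.

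The third pattern is that arrays of one group differed more than groups did. Low correlations between arrays were present before the authors' normalisation, down to 0.333 in the scanner values against 0.326 in the authors' values. The pattern was measured on the scanner values, which that normalisation did not touch, so this was no test of it. Brightness and contrast of the arrays are a candidate explanation, as the first component followed the median raw signal (r = 0.954, permutation p = 1e-05, the smallest that 100000 permutations can give). RNA quality, hybridisation and the animals themselves could each give such arrays, and no biological explanation was tested.

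Other splits of the arrays set a scale for the counts of calls. For 5th reinfection, 1 of 35 splits, the real one, called as many as 22 sequences, and the highest other called 0. That is the smallest share the design allows, and no other count of calls stood out from its splits. Neither chance nor an effect of array structure is excluded by this. With the real residuals of whole arrays shuffled, 4351 of 5303 simulated calls labelled 5th reinfection were false, and 0 of 902 labelled primary infection. These counts pool 10 repeats, so they show that runs of false calls can occur. They do not give the share of false calls among the 22. For primary infection all 35 splits called at least as many as the real 0, which they must, so this comparison decides nothing. The highest other called 17962, and that split parted 4 bright arrays from dim ones with a brightness gap of 1.59, so it follows the structure of the arrays. For the control groups all 35 splits called as many as the real 0, which decides nothing either, and the highest other called 0. For the difference 7 of 100 draws called at least 1, so chance could not be excluded, and the highest, 21953, points to some structure of the arrays, which was not traced to brightness. For lists, chance could not be excluded in any contrast: 10 of 35 splits called at least 4 in primary infection (highest other 7), 7 of 35 at least 3 in 5th reinfection (highest other 7), 43 of 100 at least 2 for the difference (highest other 9) and 15 of 35 at least 3 for the control groups (highest other 7).

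For the difference between the infections the neutrophil list had a median of 0.82 and oxidative phosphorylation -0.51, and both calls were lost with an estimated correlation (adjusted p = 0.638 for each). Among 123 sets of 4 values, 3 held a value whose gap to the others exceeded Dixon's 95% critical value, where chance gives about 1 set in 20. SPLUNC 2A was 10.52 in naive control replicate 3 and 10.89 to 10.94 in the others. CYP4F11 was 6.64 in primary infection replicate 2 and 8.23 to 8.41 in the others. The secretory IgM heavy chain was 7.09 in naive control replicate 2 and 7.74 to 7.78 in the others.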

How the results depend on the processing

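The alternatives named here as covariate, block, dim arrays, residual components and geometric mean were chosen after the result was seen, and the others were planned. Of 3794 values of named genes under an alternative, 3458 kept direction and side of the threshold, 125 lost it, 193 gained it and 18 reversed. In primary infection limma's count stayed 0 with each array left out.

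Called sequences in 5th reinfection (22) were 10 with loess, 7 with median scaling, 5 with the authors' values, 13 with a trended robust spread, 49 with only the compared groups, 52 with the covariate, 0 on the dim arrays, 10 with geometric means, and 6 to 67 with 1 array left out. The difference (1) gave 2 without background correction or filter, 0 with loess, median scaling or the stricter filter, 2 with the covariate, 0 on the dim arrays and 1 to 4 with 1 array left out. Primary infection gave 5 with the covariate and 2 with the block. Array weights, which ran from 0.0606 to 42.9 over the arrays, gave 4276, 17695, 13032 and 22148 for primary infection, 5th reinfection, difference and control groups, and residual components 5246, 10274, 11443 and 16010, where p-values are too small by construction. The control groups gave 0 with each array left out.

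Called lists were 1, 0, 0 and 0 with an estimated correlation, in the same order. 5th reinfection (3) gave 8 with the covariate, 8 with the block, 11 on the dim arrays, 6 with residual components and 2 to 7 with 1 array left out. The difference (2) gave 4 with the mean over sequences, 9 with median scaling, 1 with the covariate, 0 with the block, 0 on the dim arrays, 6 with residual components and 2 to 3 with 1 array left out. Primary infection (4) gave 2 on the dim arrays and 2 to 8 with 1 array left out. The control groups (3) gave 1 with loess, 5 with the block, 6 on the dim arrays and 2 to 5 with 1 array left out.

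The correlation between the infections' fold changes (-0.218) reversed to 0.638 with the covariate, 0.710 with the block, 0.292 on the dim arrays, 0.217 and 0.0209 without naive control replicates 1 and 3, 0.537 and 0.105 without primary infection replicates 2 and 3, and 0.180 without attenuated control replicate 1. With 1 array left out it ran from -0.449 to 0.537. Shared calls (0) were 5, 2 and 229 with the covariate, the block and residual components. They were 0 with each array left out, as they must be where primary infection had 0 calls. Median scaling moved the median of all sequences in the difference to -0.17.

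Genes that reversed had small or unstable values. CFI in the difference was 0.022 with loess, 0.11 with the covariate, 0.15 with the block and -0.30 to 0.11 with 1 array left out, above 0 without primary infection replicate 2, attenuated control replicate 3 or 5th reinfection replicate 1. PIGR in 5th reinfection was -0.27 with median scaling, C3 was -0.053 on the dim arrays, and COX4I1 in the difference was 0.049 with geometric means. In primary infection array weights gave SPLUNC 2B 0.13, SPLUNC 2A 0.012, CATHL2 0.21, CATHL3 0.19, MCM4 -0.038 and FBLN1 -0.0040, and with 1 array left out S100A9 ran from -0.72 to 0.039, CATHL2 from -1.13 to 0.060 and MPO from -1.29 to 0.092, each highest without replicate 2. Fewer arrays may play a part where counts fell on the dim arrays, but counts of lists rose there in 5th reinfection and the control groups. No cause was tested for these changes. Each probe by itself, a median over probes and a slide batch were not run, because the reports hold no single probes and each barcode holds 1 array. For the difference only the compared groups is the fit already used. No paired analysis was possible because the labels give no shared replicate numbers. Dim sequences limit what can be seen: those below the 25th percentile were not tested.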

Other observations

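The lists were planned, and setting 4 of them side by side at the end was chosen after the result was seen.

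Tuft cell genes, markers of the chemosensory cells that sense helminths, did not pass in either infection. The list's median was 0.38 in primary infection (4 of 5 positive, adjusted p = 0.0795) and 0.36 in 5th reinfection (4 of 5 positive, adjusted p = 0.103). ALOX5, a leukotriene-forming enzyme, had 0.66 ± 0.26 and 0.53 ± 0.26. Acute phase genes had a median of -0.18 with the test pointing up in primary infection (adjusted p = 0.731) and 0.52 in 5th reinfection (adjusted p = 0.145), where ceruloplasmin, CP, had 0.67 ± 0.22 and haptoglobin, HP, 0.68 ± 0.29 while FGA had -0.94 ± 0.35. Epithelial junction genes had medians of 0.12 and 0.12 (adjusted p = 0.0958 and 0.227), with CLDN2 at 1.04 ± 0.44 and 1.36 ± 0.44. Parietal cell genes, which make gastric acid, stood at 0.09 and -0.05 (adjusted p = 0.554 and 0.637). Chief cell genes stood at 0.03 and 0.04, the second with the test pointing down (adjusted p = 0.573 and 0.573). PGC, a pepsinogen, had 1.17 ± 0.47 in primary infection and 1.49 ± 0.47 in the attenuated against the naive control, where it and IL17RB, a tuft cell receptor for IL-25 (1.55 ± 0.53), were higher when adjusted over their lists alone, as were PIGR and CR2 in the B and plasma cell list. Enteroendocrine genes stood at -0.03 and -0.25 (adjusted p = 0.595 and 0.145), with ghrelin, GHRL, at -1.38 ± 0.74 and somatostatin, SST, at -1.41 ± 0.76 in 5th reinfection.

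None of the other immune lists passed. Type 2 immunity, of which 9 of 22 genes were measured, had medians of -0.21 and 0.25 in primary infection and 5th reinfection (adjusted p = 0.923 and 0.692), and its test pointed up in both. Type 1 and interferon genes had -0.44 and 0.39 (adjusted p = 0.142 and 0.171), mast cell genes 0.08 and 0.23 (0.554 and 0.573), and eosinophil genes, with 2 of 10 measured, -0.10 and 0.14 (0.554 and 0.919). Macrophage and dendritic cell genes had -0.02 and 0.03, the second with the test pointing down (0.615 and 0.948), T and natural killer cell genes -0.15 and 0.30 (0.481 and 0.145), B and plasma cell genes 0.11 and 0.24 (0.325 and 0.235), and MHC class II genes -0.01 and 0.23 (0.954 and 0.227). Smooth muscle had 0.02 and -0.04 (0.595 and 0.921) and endothelium 0.18 and 0.07 (0.595 and 0.919), with a mean of -0.02 in primary infection. For the difference the test pointed up for type 2 immunity and tuft cell genes against medians of -0.12 and -0.13, and the median and mean differed in sign for B and plasma cell, endothelium and epithelial junction genes (0.06 and -0.01, -0.06 and 0.09, -0.06 and 0.05). Lists of tissue that gastric mucosa should hold little of were negative in primary infection and positive in 5th reinfection: intestinal epithelium had -0.37 and 0.40 (0.382 and 0.103), squamous epithelium -0.44 and 0.34 (0.191 and 0.342) and red blood cell genes -0.45 and 0.55 (0.412 and 0.145). For the difference, intestinal epithelium had 0.77 (0.0769) and type 1 and interferon genes 0.95 (0.0769). None of these passed, and heat shock genes had 0.17 and -0.15 (0.120 and 0.573). Neutrophil genes in 5th reinfection had 0.25 with 8 of 8 positive (0.145).

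Medians of neutrophil, intestinal, squamous and red blood cell lists thus share a sign within each contrast. Their estimated correlations between genes were 0.693, 0.663, 0.917 and 0.876, and each list's adjusted p was 0.638 for the difference with an estimated correlation. The squamous list's median percentile within an array was 16.87 to 37.48 on some dim arrays and 57.03 to 79.73 on all others. The low ones were primary infection replicates 2 and 3, naive control replicate 4, attenuated control replicates 1 and 3 and reinfection replicate 2. Primary infection held more of them than its control and reinfection fewer, matching the squamous signs. The neutrophil list was not tested for this, so array differences stay open for it.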
